A study of Mus musculus with 9 samples.

How the data were processed

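The series profiled polyadenylated RNA of mouse corneal epithelial cells, a cultured line that the labels call iCell-0093a, kept at 21%, 8% or 1% oxygen. Each oxygen level had 3 libraries, 9 in all. Per the labels, RNA was extracted with TRIzol and 1 µg of total RNA entered an Illumina TruSeq Stranded mRNA preparation, which selects polyadenylated RNA. The labels do not say whether replicates were separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

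The authors deposited a table of gene-level FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), with 26445 entries and a column for each library. Per the submitters' processing notes, the tools were FastQC 0.11.8, cutadapt 1.9.1, HISAT2 2.0.4 and StringTie 1.3.4d, and the genome build was mm10. The annotation release, the strand setting and the way transcripts were combined into genes are not given in the sources used here. Reads that a gene shares with a near-identical copy, an overlapping gene or an antisense gene may therefore have been divided in an unknown way, which makes ribosomal protein genes (with their processed pseudogenes), heat shock genes and short RNA genes inside other transcripts uncertain.

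The deposited FPKM values carry no read counts, and sequencing depth is unknown. The smallest value above 0 was 1e-06. In genes with a single annotated transcript, 6% of the values above 0 lay below what 1 fragment out of 100000000 would give, so the values were not whole multiples of a read and depth could not be recovered. No counting interval or detection floor is given for this reason. The FPKM sums of the libraries lay between 317704 and 333178.

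Gene identifiers were matched to GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the 26445 entries 26378 matched by identifier, and 25638 of those carried the same symbol. Entries sharing a symbol (43 symbols on 89 entries) were kept apart by identifier. Coordinates are 1-based and come from that annotation.

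Differences were tested in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 9 libraries entered, which left 11856 genes. A fold change on this scale understates the change of genes with low FPKM. All 9 libraries entered a single model of group means with a mean-variance trend, so the comparisons share an estimate of the spread. Where 1 level is more spread than the others, that estimate can be too small for its comparisons and too large for the remaining one. The comparisons were 8% against 21%, 1% against 21% and 1% against 8% oxygen, plus a moderated F test across the 3 levels. P-values were adjusted by the Benjamini-Hochberg method within each comparison and a gene was called at an adjusted p of 0.05, with no limit on the fold change. All tests were two-sided. Positive log2 fold changes mean higher values at the lower oxygen level.

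Before the data were examined, 44 gene lists were fixed, covering hypoxia, mitochondria, autophagy, stress responses, growth, inflammation and cell type markers. The model, the alternatives and the rule for named genes were also fixed before the data were examined. The 36 lists with at least 5 tested members were compared with the remaining genes by limma's camera test with its preset correlation of 0.01, adjusted over the 36 lists. Camera with a correlation estimated from the data and limma's fry test were run beside it, and members of each list were also counted as called with p adjusted over the list alone. Fry tests whether the members of a list move, on balance, one way and does not compare them with other genes. Over all tested genes the median log2 fold change was −0.0399 at 8% against 21%, −0.0471 at 1% against 21% and −0.0031 at 1% against 8%. Because camera compares a list with the remaining genes, its direction can differ from the sign of the list's median. With an estimated correlation no list passed in any comparison, and none did so with any single library left out, with either other filter, with either rescaling, in the fits to 6 libraries or with protein-coding genes only, settings added after the data had been seen. At the preset correlation, wrong splits of the 6 libraries called up to 10 lists at 8% against 21% (5 real). They called up to 11 at 1% against 21% (9 real) and 12 at 1% against 8% (13 real). A camera call at that correlation is therefore weak evidence of a shift with oxygen.

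Genes are named in the text by 4 criteria. These were the 8 largest changes per direction among called genes with a mean of at least 5 FPKM and groups that did not overlap, up to 4 called members of each list, 18 genes fixed in advance for hypoxia, mitophagy and corneal identity, and called genes that were most extreme at 8% oxygen or went in opposite directions. Genes outside these criteria are marked as chosen after their values were seen. Krt12 and Krt5, 2 of the 18, were not analysed here. Some other genes that meet the criteria are not reported here.

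The procedure was tested on simulated data with the spread of these libraries, in 10 runs with 200 of the 11856 genes changed. A log2 change of 0.5 was recovered for 55.2% of genes in 8% against 21%, 50.8% in 1% against 21% and 54% in 1% against 8% oxygen. For a log2 change of 1 the shares were 89.8%, 90.6% and 87.4%. Of the calls in these comparisons, 6.13%, 4.18% and 4.14% were false. A list shifted by 0.3 was called in 10 of 10 runs. Simulated genes varied independently of each other, so these runs do not cover lists whose members vary together. In the real data the correlation estimated within a list reached 0.9301 (cell cycle, G2 and M phase). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

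Alternatives covered the pseudocount (0.1 and 0.01), the filter (none, or a mean of at least 5 FPKM), rescaling by median ratios, quantile normalization, limma without the trend or with robust estimates, a fit to only the 6 libraries compared, a replicate block, a fold limit, the other list tests and leaving out each library. A restriction to protein-coding genes was added after the data had been seen. Overlap between the comparisons with 21% oxygen was set against 100 simulations of unchanged groups that share simulated 21% libraries. There all 9 libraries were drawn anew, with genes varying independently at their fitted spread.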

Results

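Messenger RNA levels were measured in mouse corneal epithelial cells cultured at 21%, 8% or 1% oxygen, with 3 libraries per level. The series title concerns mitophagy and mitochondrial genes under physiological and pathological low oxygen, and the labels do not say which oxygen level stands for which state. The libraries held between 19837 and 20569 genes above 0 FPKM, and genes of the mitochondrial genome made up 6.02% to 8.52% of the FPKM sum. Pearson correlations of log2 values across genes, which are not independent replicates, lay between 0.9708 and 0.9818 within 21% oxygen, 0.9806 and 0.9838 within 8% and 0.9836 and 0.9857 within 1%. Between levels they lay between 0.9563 and 0.9812. The first principal component held 31.4% of the variance and the second 18.3%. The 21% oxygen libraries were the most spread, with 21% replicate 3 at 27.48 and 10.7 on these components while 21% replicates 1 and 2 lay at 14.45 and −12.82 and at 9.15 and −21.93.

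The cells carried transcripts of a simple epithelium at high levels and little of the corneal differentiation programme. Over the 9 libraries, mean FPKM was 582 for Krt18 and 572 for Krt8 (simple epithelial keratins), 86.5 for Epcam, 60.2 for Cdh1 (E-cadherin) and 67.2 for Krt14 (basal keratin). Pax6, the eye field transcription factor, did not exceed 0.0208 FPKM in any library, and Trp63, the basal epithelial regulator, did not exceed 0.836. Of 24 stromal fibroblast and keratocyte markers 7 reached 1 FPKM in at least 3 libraries. Among these were Vim (vimentin) at 857 FPKM, S100a4 at 750, the matrix genes Fbln2 at 77.4 and Col6a1 at 15.8, the transcription factor Twist1 at 35.7 and the receptor Pdgfra at 7.64, whereas the stromal matrix genes Lum, Dcn and Col1a1 stayed at or below 1.02 FPKM in every library. Among leukocyte markers, Ptprc reached at most 0.0101 FPKM, and Cd68, a lysosomal protein of macrophages, averaged 34.8. Cd68 rose from 25.4 ± 5.71 FPKM at 21% to 43.3 ± 1.91 at 8% oxygen (SD, n = 3, log2 fold change 0.77, SE 0.159, adjusted p = 0.0123). Csf1r, a macrophage receptor, rose from 0.445 ± 0.124 to 1.32 ± 0.267 FPKM (adjusted p = 0.00658).

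The first comparison asked what differed between 8% and 21% oxygen. Il1rl1, the interleukin 33 receptor (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415 on GRCm38), rose from 6.98 ± 0.964 to 27.1 ± 1.81 FPKM (SD, n = 3, log2 fold change 1.82, SE 0.089, adjusted p = 0.000116). Angptl7, a secreted angiopoietin-like protein, rose from 3.86 ± 1.19 to 15.1 ± 0.873 FPKM (1.76, SE 0.19, adjusted p = 0.00143). Ccn1, a matricellular protein, rose to 761 ± 30.8 from 297 ± 33.9 FPKM (1.36, SE 0.093, adjusted p = 0.000424). Dusp1, a MAP kinase phosphatase, rose to 19.4 ± 3.75 from 6.82 ± 1.42 (1.38, adjusted p = 0.00325). Areg, the growth factor amphiregulin, fell from 29.4 ± 2.13 to 5.96 ± 0.953 FPKM (−2.14, SE 0.181, adjusted p = 0.000895). Csf3, the granulocyte growth factor, fell from 128 ± 59 to 34.0 ± 2.94 (−1.78, SE 0.275, adjusted p = 0.00442). The metallothionein Mt2 (−1.63), the metal transporter Slc39a14 (−1.44), the RNase P and MRP subunit Pop1 (−1.34), the transferrin receptor Tfrc (−1.33) and the AP-1 member Fosl1 (−1.32) also fell, with adjusted p between 0.00036 and 0.011. All of these calls were kept in every one of the 19 alternatives run for single genes.

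**Figure D1:**
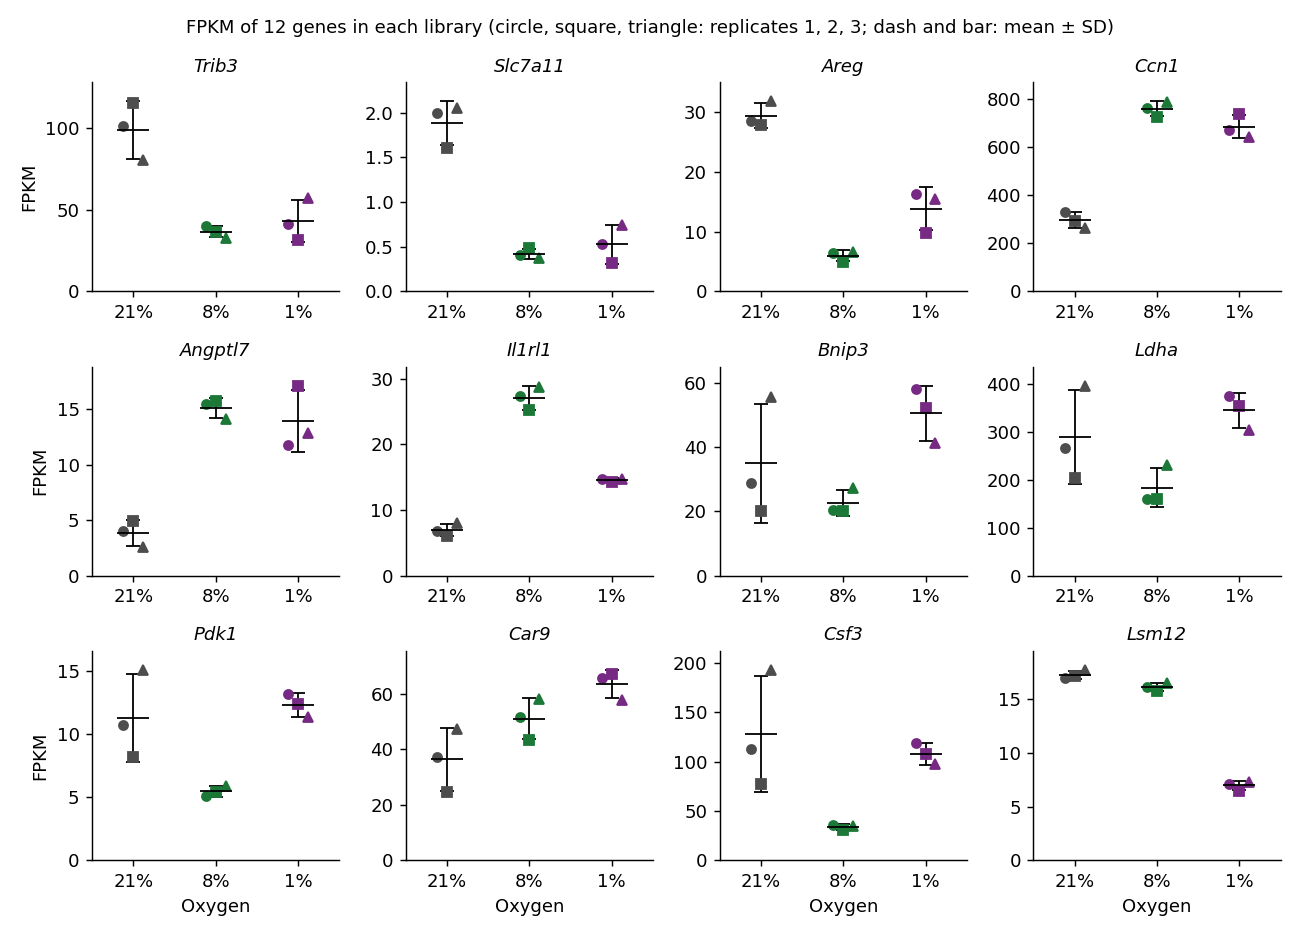
FPKM of 12 genes in each library (linear axes from 0), by oxygen level, where circles, squares and triangles are replicates 1, 2 and 3 and the dash with its bar is the mean ± SD. Trib3, Slc7a11 and Areg lay lower and Ccn1 and Angptl7 higher at both reduced oxygen levels than at 21%, Lsm12 lay at 6.96 FPKM at 1% oxygen against 16.1 at 8%, and Bnip3, Ldha, Pdk1 and Csf3 had wide SDs at 21% oxygen.

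Genes of the ATF4 integrated stress response, which serve amino acid supply and the response to stalled translation, fell together at 8% oxygen. Of the 22 tested, 15 fell and none rose (15 also when adjusted over the list alone). In 21 of 22 the estimate was negative and the median log2 fold change was −0.51 (camera adjusted p = 1.28e-06; adjusted p = 0.709 with an estimated correlation). The pseudokinase Trib3 fell from 98.8 ± 17.5 to 36.5 ± 3.49 FPKM (−1.40, SE 0.209, adjusted p = 0.00385). The cystine transporter Slc7a11 fell from 1.88 ± 0.245 to 0.418 ± 0.0573 (−1.02, adjusted p = 0.00194), and the cysteine-forming enzyme Cth by 0.90 (adjusted p = 0.0104). Cytosolic ribosomal protein genes moved the other way. Of 69 tested, 20 rose and none fell (35 rose when adjusted over the list alone). In 66 the estimate was positive and the median was 0.19 (camera adjusted p = 3.86e-12; adjusted p = 0.709 with an estimated correlation). Rpl37a rose from 199 ± 9.43 to 262 ± 11.6 FPKM (0.40, adjusted p = 0.00352) and Rpl24 from 586 ± 53.7 to 760 ± 28.4 (0.38, adjusted p = 0.0117). Reads shared with processed pseudogenes leave this family uncertain.

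Among the lists of nuclear genes for mitochondrial proteins, camera called only mitochondrial chaperones and proteases at 8% oxygen. Counts of lower members stand here beside 1772 lower among all 11856 genes. In that list, 6 of 16 fell (8 adjusted over the list alone) with a median of −0.29 (camera adjusted p = 0.0206; adjusted p = 0.709 with an estimated correlation; 0.0688 without 21% replicate 2). The chaperone Trap1 fell from 47.2 ± 0.42 to 32.2 ± 2.65 FPKM (−0.54, SE 0.066, adjusted p = 0.002). The protease Parl fell by 0.50 (adjusted p = 0.00133), the protease Lonp1 by 0.34 (adjusted p = 0.00384) and the chaperonin Hspd1 by 0.39 (adjusted p = 0.00485). Among 31 mitochondrial protein import genes 10 fell and 1 rose (10 and 1 adjusted over the list alone). Among 76 genes of the mitochondrial ribosome 17 fell and 5 rose (18 and 6 adjusted over the list alone). Neither list passed camera (adjusted p = 0.102 and 0.0964). Fry, which asks whether members move one way on balance without comparing them with other genes, gave 0.0087 and 0.00877. Camera called mitochondrial protein import without 21% replicate 3 (0.0217), the mitochondrial ribosome without 8% replicate 2 (0.0334) and both without the filter on low values (0.00501 and 0.000653). With an estimated correlation these gave adjusted p = 0.625, 0.672, 0.548 and 0.548. Tomm40, the outer membrane import pore, fell from 16.7 ± 1.09 to 10.9 ± 0.333 FPKM (−0.57, SE 0.061, adjusted p = 0.00142). Tfam, the mitochondrial DNA packaging factor, fell from 11.2 ± 0.789 to 7.69 ± 0.593 (−0.49, adjusted p = 0.00351) in a list of mitochondrial biogenesis and mtDNA maintenance with 1 higher and 3 lower of 19, 1 and 3 also when adjusted over the list alone (camera adjusted p = 0.29). Respiratory chain subunits went both ways. Nuclear-encoded complex I genes numbered 2 higher and 5 lower of 36, 2 and 5 also when adjusted over the list alone (camera adjusted p = 0.29). Uqcrh of complex III rose from 43.9 ± 1.08 to 82.5 ± 6.21 FPKM (0.89, SE 0.06, adjusted p = 0.000424).

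Transcripts of the mitochondrial genome itself went both ways. The messenger RNAs mt-Cytb (1085 ± 57.6 against 1969 ± 142 FPKM, −0.86, SE 0.076, adjusted p = 0.000983), mt-Nd1 (−0.54, adjusted p = 0.00479) and mt-Nd2 (−0.62, adjusted p = 0.0111) fell. The other 10 of 13 did not pass (3 fell when adjusted over the list alone; median −0.24, camera adjusted p = 0.29). With quantile normalization the list of mitochondrially encoded mRNAs passed (adjusted p = 0.0212; adjusted p = 0.698 with an estimated correlation), as it did without 8% replicate 2 (0.0426; 0.694 with an estimated correlation). That library stood apart, with 8.52% of FPKM from mitochondrial genes against 6.02% and 6.28% in 8% replicates 1 and 3, and with a median deviation of the list of 0.097 against −0.321 and −0.257. The tRNA genes mt-Tn (M, 5089 to 5159), mt-Ta and mt-Tc rose, to 84.2 ± 8.59 from 20.3 ± 2.6, 52.0 ± 6.79 from 13.0 ± 1.61 and 34.7 ± 1.02 from 9.87 ± 0.609 FPKM (2.00, 1.92 and 1.72, adjusted p = 0.000286, 0.000417 and 1.49e-05). The tRNA gene mt-Tp rose by 1.31 (adjusted p = 0.037), a call lost without 21% replicate 1, any 8% library or 1% replicate 1 or 2 (adjusted p up to 0.0988), without the filter on low values, in the fit to 6 libraries and with the replicate block. Chosen after their values were seen, the tRNA genes mt-Tk (−1.23, adjusted p = 0.016) and mt-Te (−0.23, adjusted p = 0.044) fell, while the tRNA genes mt-Ty (1.18, adjusted p = 0.0023), mt-Tr (0.94, adjusted p = 0.026) and mt-Tt (1.13, adjusted p = 0.049) and the ribosomal RNA mt-Rnr1 (0.51, adjusted p = 0.0057) rose. No alternatives were tabulated for these 6 calls. Genes this short are poorly captured in libraries of polyadenylated RNA, and how reads overlapping their neighbours were counted is not given in the sources used here.

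**Figure D2:**
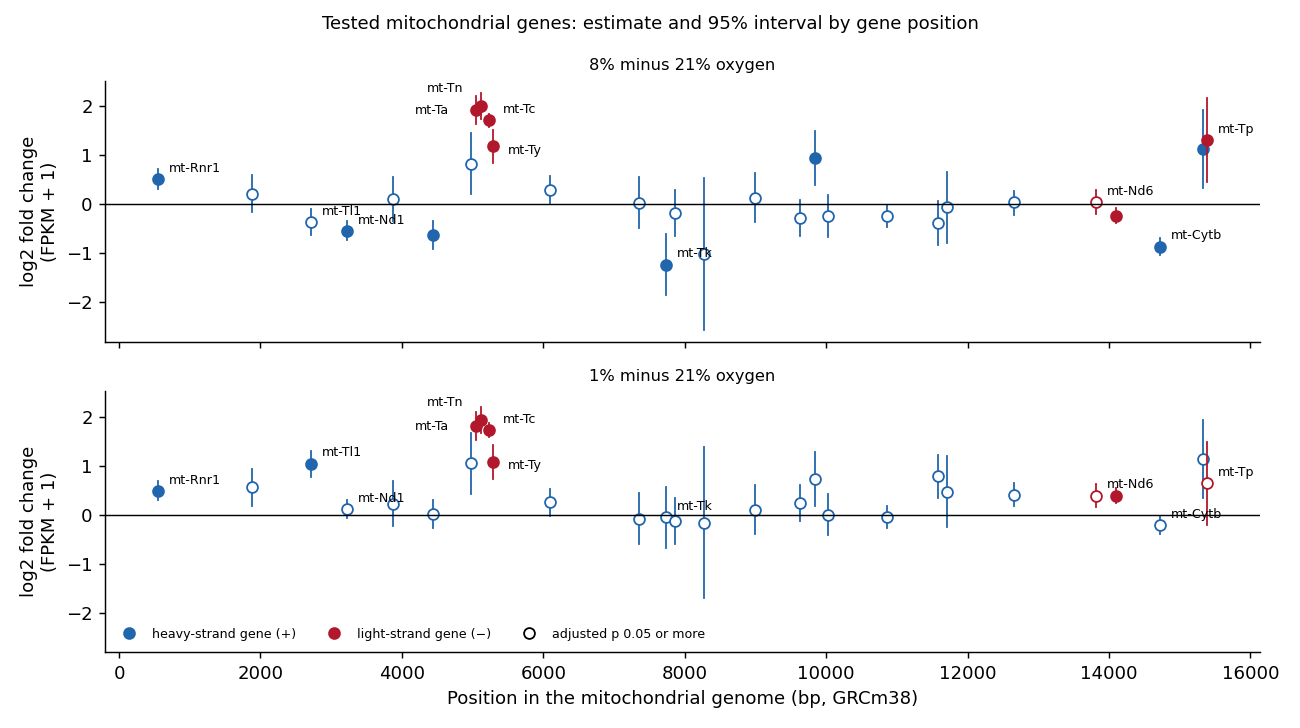
Log2 fold change with 95% interval of each tested mitochondrial gene, placed by its position on the mitochondrial genome (GRCm38), for 8% against 21% oxygen (upper) and 1% against 21% oxygen (lower). Blue marks heavy-strand and red light-strand genes and filled symbols passed at adjusted p 0.05. The neighbours mt-Ta, mt-Tn, mt-Tc and mt-Ty stand together above 1 in both panels. Also above 1 are mt-Tt in both panels (1.13 and 1.14), mt-Tp at 8% (1.31), and mt-Tw (1.05) and mt-Tl1 (1.04) at 1%.

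HIF targets, the genes usually induced when oxygen falls, did not move as a group at 8% oxygen. Outside glycolysis 3 of 33 rose and 2 fell (2 and 0 adjusted over the list alone). Their median was −0.12 and their mean −0.04 while camera pointed up (adjusted p = 0.903). Glycolysis and lactate export genes gave 3 higher and 3 lower of 18 (5 and 6 adjusted over the list alone). There the median was −0.12 and the mean −0.08 against an upward camera direction (adjusted p = 0.872). Both camera directions turned down with quantile normalization. Adm, the vasodilator adrenomedullin, rose from 2.35 ± 0.569 to 5.76 ± 0.804 FPKM (1.02, adjusted p = 0.00266). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell from 11.3 ± 3.49 to 5.46 ± 0.421 FPKM (−0.89, SE 0.177, adjusted p = 0.0107). Hif1a fell from 56.8 ± 6.91 to 42.6 ± 1.87 FPKM (−0.40, adjusted p = 0.0154; 0.0562 without 8% replicate 3). The glucose transporter Slc2a1 fell from 29.6 ± 2.8 to 22.7 ± 1.28 (−0.37, adjusted p = 0.0204; 0.0668 and 0.0611 without 8% replicate 1 or 2). Ldha stood at 184 ± 40.3 against 290 ± 97.9 FPKM (adjusted p = 0.0926; 0.0289 without 21% replicate 2). Car9, carbonic anhydrase 9, stood at 51.1 ± 7.45 against 36.4 ± 11.4 (adjusted p = 0.113; 0.0326 without 21% replicate 3).

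Among smaller groups, angiogenic growth factors and regulators rose as a list of 10 (median 0.20, camera adjusted p = 0.0267; adjusted p = 0.709 with an estimated correlation). Adm, Thbs1 and Pdgfb rose and Vegfa, the main endothelial growth factor, fell (4 rose and 1 fell adjusted over the list alone). Thbs1, an inhibitor of angiogenesis, rose from 105 ± 18.9 to 219 ± 17.2 FPKM (1.07, SE 0.125, adjusted p = 0.00176). Vegfa fell by 0.33 (adjusted p = 0.0349). The call of Vegfa was lost after either rescaling, without the filter on low values, in the fit to 6 libraries, with the replicate block and without any 21% or 8% library or 1% replicate 2 (adjusted p between 0.0298 and 0.102 over its 19 alternatives), and that of Pdgfb without 8% replicate 3 (0.0558). This list's call was lost without the filter on low values (adjusted p = 0.29), at a mean of at least 5 FPKM (0.2) and without 8% replicate 1 (0.05 after rounding), and its median was 0.11 without 21% replicate 3. Of 16 heat shock genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.174). The chaperone Hspa8 rose from 317 ± 8.85 to 556 ± 35.8 FPKM (0.81, SE 0.063, adjusted p = 0.00073) and Hspa4l from 15.2 ± 2.65 to 34.1 ± 1.55 (1.13, SE 0.106, adjusted p = 0.000983). Corneal and stratified epithelium markers gave 5 higher and 2 lower of 24 (5 and 2 adjusted over the list alone; camera adjusted p = 0.159, and 0.0334 without 21% replicate 3, where an estimated correlation gave 0.681). The desmosomal Dsp rose (0.54, adjusted p = 0.00352) and the transcription factor Klf4 fell (−0.55, adjusted p = 0.00789).

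DNA replication genes fell as a list at 8% oxygen, with a median of −0.51 and 34 of 36 estimates negative (camera adjusted p = 0.00131; adjusted p = 0.709 with an estimated correlation). Limma called 4 members lower (Pola1, Mcm10, Mcm7 and Pole, all of the replication machinery), 0 when adjusted over the list alone, and 14 lay lower at an unadjusted p under 0.05. All 4 calls were lost without 8% replicate 1 or 2 (adjusted p up to 0.0732, 0.06, 0.0816 and 0.119 with a library left out). Those of Pola1, Mcm7 and Pole were also lost without 21% replicate 1 or 8% replicate 3, and that of Pole without 21% replicate 3 or any 1% library. Fry did not call the list (adjusted p = 0.155). The list DNA replication, G1 and S phase stood apart in 1 library. Its median deviation from each gene's mean over the 9 libraries was 0.826 in 21% replicate 3, 0.116 and −0.233 in 21% replicates 1 and 2, and −0.319, −0.312 and −0.254 at 8% oxygen. Without 21% replicate 3 the list's median went from −0.51 to −0.21 (camera adjusted p = 0.0334), and without 21% replicate 2 to −0.82. Without the filter on low values the calls of all 4 genes were lost as well, and in a fit to only the 6 libraries compared those of Pola1, Mcm7 and Pole.

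In all, 2765 of 11856 genes were called between 8% and 21% oxygen by limma, 993 higher and 1772 lower, with a median absolute log2 fold change of 0.396. The groups did not overlap in 4847 genes, 40.88% of those tested, where chance gives 10%. Of the calls 35.9% were higher, against 50% after median-ratio rescaling and 46.6% after quantile normalization, so the balance of directions rested on the scaling. Leaving out 21% replicate 1, 8% replicate 1, 8% replicate 2 or 8% replicate 3 lowered the calls to 1806, 1599, 1791 and 1479. A fit to only the 6 libraries compared called 1606.

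The second comparison asked what differed between 1% and 21% oxygen. Lsm12, a protein of the RNA-binding LSM family (ENSMUSG00000020922, chromosome 11, 102162497 to 102185296), fell from 17.2 ± 0.393 to 6.96 ± 0.428 FPKM (SD, n = 3, log2 fold change −1.20, SE 0.056, adjusted p = 7.66e-05). Mapk14, the p38 alpha kinase, fell from 17.5 ± 0.381 to 7.11 ± 1.33 (−1.20, SE 0.12, adjusted p = 0.00523). Slc39a14 fell from 16.0 ± 0.412 to 7.58 ± 0.873 FPKM (−0.99, SE 0.09, adjusted p = 0.00405). Angptl7 rose from 3.86 ± 1.19 to 13.9 ± 2.8 FPKM (1.64, SE 0.19, adjusted p = 0.0073) and Ccn1 from 297 ± 33.9 to 685 ± 48.4 (1.21, SE 0.093, adjusted p = 0.0014). Thbs1 rose from 105 ± 18.9 to 241 ± 4.14 (1.21, SE 0.125, adjusted p = 0.0061). These calls were kept in all 19 alternatives, as were those of mt-Tn (1.93), mt-Ta (1.81) and mt-Tc (1.72). Ccn2, another matricellular protein, rose from 26.7 ± 4.79 to 62.7 ± 2.6 FPKM (1.22, SE 0.167, adjusted p = 0.0132), a call lost without 1% replicate 1 or 2 (adjusted p up to 0.0609).

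The ATF4 integrated stress response list fell at 1% oxygen as well, with 11 of 22 lower and none higher (16 adjusted over the list alone). All 22 estimates were negative, with a median of −0.56 (camera adjusted p = 5.84e-11; adjusted p = 0.369 with an estimated correlation). Slc3a2, the partner chain of amino acid transporters, fell from 87.6 ± 11.6 to 49.1 ± 4.21 FPKM (−0.82, SE 0.101, adjusted p = 0.00819). Trib3 fell to 43.1 ± 13 FPKM (−1.20, adjusted p = 0.0249) and Slc7a11 to 0.527 ± 0.216 (−0.92, adjusted p = 0.0118), calls that were lost without 21% replicate 1 or 1% replicate 1 (adjusted p up to 0.0956 and 0.0545). That of Trib3 was also lost without 21% replicate 2 or 1% replicate 2. The median of mitochondrial chaperones and proteases was −0.13, with 1 of 16 lower, namely Parl (−0.44, adjusted p = 0.00738), and 4 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.445 with an estimated correlation; 0.0881 without 21% replicate 2).

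HIF targets outside glycolysis rose as a list at 1% oxygen, with 4 of 33 higher and none lower (8 adjusted over the list alone) and a median of 0.14 (camera adjusted p = 1.7e-05; adjusted p = 0.312 with an estimated correlation; median 0.21 without 21% replicate 3 and 0.09 without 1% replicate 1). Among them were Adm (0.86, adjusted p = 0.0188), the repressor Bhlhe40 (0.85, adjusted p = 0.0473) and the prolyl hydroxylase Egln3 (0.29, adjusted p = 0.0457). Glycolysis and lactate export genes rose too, with 2 of 18 higher (6 adjusted over the list alone) and a median of 0.29 (camera adjusted p = 7.32e-06; adjusted p = 0.402 with an estimated correlation; median 0.45 without 21% replicate 3). Aldoa, an aldolase (ENSMUSG00000030695, of 2 entries with this symbol), rose from 351 ± 59.2 to 539 ± 40.5 FPKM (0.63, SE 0.134, adjusted p = 0.0424) and Aldoc by 0.56 (adjusted p = 0.0459). The calls of Bhlhe40, Egln3, Aldoa and Aldoc were lost in 11 or 12 of the 19 alternatives, with adjusted p up to 0.157. Among these were leaving out 21% replicate 1 or 2, 8% replicate 1 or 3 or any 1% library, and, for the last 3 genes, 8% replicate 2. That of Adm was lost without 21% replicate 1 and without 1% replicate 1 or 2 (adjusted p up to 0.0829). Car9 stood at 63.5 ± 4.99 against 36.4 ± 11.4 FPKM (0.83, adjusted p = 0.0626; 0.025 without 21% replicate 3).

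Endoplasmic reticulum chaperone genes, the unfolded protein response list, rose at 1% oxygen with 5 of 19 higher (5 adjusted over the list alone) and a median of 0.23 (camera adjusted p = 7.32e-06; adjusted p = 0.402 with an estimated correlation; median 0.13 without 1% replicate 3). At 8% against 21% oxygen 5 of the list rose and 1 fell (5 and 1 adjusted over the list alone; median 0.08, camera adjusted p = 0.057; adjusted p = 0.709 with an estimated correlation). Camera called it there without the filter on low values, after median-ratio rescaling, in the fit to 6 libraries, with protein-coding genes only and without 21% replicate 3, 8% replicate 1 or 1% replicate 2 or 3 (adjusted p between 0.0213 and 0.0497; adjusted p between 0.59 and 0.794 with an estimated correlation). Calr rose from 105 ± 11.1 to 174 ± 32.5 FPKM (0.71, SE 0.128, adjusted p = 0.0274) and Hsp90b1 from 153 ± 15.7 to 233 ± 8.95 (0.60, SE 0.087, adjusted p = 0.0151), and Sdf2l1 rose by 0.70 (adjusted p = 0.0222). All 3 calls were lost without 21% replicate 1 or 1% replicate 1 (adjusted p up to 0.094, 0.0661 and 0.0939). That of Calr was also lost without 21% replicate 2 or 8% replicate 1, that of Hsp90b1 without 1% replicate 2, and that of Sdf2l1 without 21% replicate 2 or 1% replicate 3. Inflammatory cytokines and NF-kappaB targets gave 2 of 19 higher (4 adjusted over the list alone) and a median of 0.17 (camera adjusted p = 4.59e-05; adjusted p = 0.312 with an estimated correlation). The neutrophil chemokine Cxcl5 rose from 425 ± 3.83 to 621 ± 48.3 FPKM (0.55, SE 0.068, adjusted p = 0.00819). Angiogenic growth factors and regulators gave 3 of 10 higher (4 adjusted over the list alone), namely Thbs1, Adm and Pdgfb (median 0.09, camera adjusted p = 0.000361; adjusted p = 0.312 with an estimated correlation; median 0.16 and 0.06 without 21% replicates 2 and 3). The call of Pdgfb (0.47, adjusted p = 0.011) was lost without 1% replicate 1 (0.0514). Corneal and stratified epithelium markers gave 2 of 24 higher, among them Krt19 (0.51, adjusted p = 0.0188), 2 also when adjusted over the list alone (median 0.11, camera adjusted p = 0.0117; adjusted p = 0.424 with an estimated correlation; median 0.06 without 21% replicate 2). The call of Krt19 was lost without 21% replicate 1 and without 1% replicate 1 or 2 (adjusted p up to 0.0853).

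Cytosolic ribosomal protein genes lay higher at 1% oxygen in 65 of 69 (median 0.15, camera adjusted p = 6.66e-15; adjusted p = 0.424 with an estimated correlation). Their median deviation was −0.222 in 21% replicate 3, −0.059 and −0.057 in 21% replicates 1 and 2, and −0.004, 0.026 and 0.061 at 1% oxygen, and without 21% replicate 3 the median was 0.09. Limma called 0 of them, 0 also when adjusted over the list alone, with 25 higher at an unadjusted p under 0.05. Camera after quantile normalization, and fry, did not call the cytosolic ribosomal proteins (adjusted p = 0.382 and 0.0687) or the corneal and stratified epithelium markers (0.0729 and 0.104). Fry also did not call glycolysis (0.0841) or the unfolded protein response (0.0679). For DNA replication, G1 and S phase limma called 0 of 36, 0 also when adjusted over the list alone (2 lower at an unadjusted p under 0.05; median −0.14). The list did not pass (camera adjusted p = 0.431). There the direction depended on the 21% library left out. Camera pointed up without 21% replicate 3 (adjusted p = 0.000434; adjusted p = 0.587 with an estimated correlation) and down without 21% replicate 2 (adjusted p = 4.04e-05; adjusted p = 0.647 with an estimated correlation). In a fit to only the 6 libraries compared the calls of Slc3a2, Slc7a11, Trib3, Adm, Calr, Hsp90b1, Sdf2l1, Cxcl5, Pdgfb and Krt19 at 1% against 21% oxygen were lost as well. The replicate block ended those of Trib3, Calr, Sdf2l1, Pdgfb and Krt19, and testing without the filter on low values those of Trib3 and Calr.

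Between 1% and 21% oxygen limma called 503 genes, 160 higher and 343 lower, and 3354 genes (28.29%, where chance gives 10%) had groups that did not overlap. Of the calls 31.8% were higher, against 54.3% after median-ratio rescaling and 47.7% after quantile normalization. The count depended on single libraries. It was 76, 283 and 883 without 21% replicates 1, 2 and 3, 169 and 296 without 8% replicates 1 and 3, and 63, 75 and 208 without 1% replicates 1, 2 and 3. A fit to only the 6 libraries compared, which takes no spread from the 8% libraries and has fewer degrees of freedom, called 64. Of 54 named calls 12 were kept in all alternatives.

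The third comparison asked what differed between 1% and 8% oxygen, both below room air. Lsm12 fell from 16.1 ± 0.387 to 6.96 ± 0.428 FPKM (SD, n = 3, log2 fold change −1.11, SE 0.056, adjusted p = 0.000296), the single call kept in all 19 alternatives. The tRNA gene mt-Tl1 rose from 85.0 ± 6.69 to 226 ± 22.1 FPKM (1.40, SE 0.114, adjusted p = 0.00722; 0.0683 without 8% replicate 3 and 0.0798 with the replicate block). Il1rl1 fell from 27.1 ± 1.81 to 14.6 ± 0.244 FPKM (−0.85, SE 0.089, adjusted p = 0.0276). The inositol transporter Slc5a3 fell from 10.6 ± 0.715 to 5.14 ± 0.364 (−0.91, adjusted p = 0.0428) and Il18rap, an interleukin 18 receptor chain near Il1rl1 on chromosome 1, from 16.3 ± 0.578 to 11.3 ± 0.506 (−0.49, adjusted p = 0.0428). Lcn2, the iron-scavenging lipocalin, rose from 6.43 ± 0.219 to 12.8 ± 0.399 FPKM (0.89, adjusted p = 0.0404), mt-Cytb from 1085 ± 57.6 to 1700 ± 57.1 (0.65, adjusted p = 0.0403) and mt-Nd1 from 933 ± 20.2 to 1474 ± 109 (0.66, adjusted p = 0.0428). For Il1rl1, Slc5a3, Il18rap, Lcn2, mt-Cytb and mt-Nd1 the 1% mean lay closer to the 21% mean than the 8% mean did, with Lcn2 at 12.7 ± 2.18 and mt-Nd1 at 1355 ± 115 FPKM at 21%. The calls of these 6 genes were lost in 9 to 11 of the 19 alternatives, including without 21% replicate 1 or any 8% or 1% library (adjusted p up to 0.199).

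Several lists fixed in advance lay higher at 1% than at 8% oxygen although few of their members passed singly. Inflammatory cytokines and NF-kappaB targets had a median of 0.58 with 18 of 19 estimates positive. In this list 1 gene was called (Lcn2) and 12 when adjusted over the list alone (camera adjusted p = 3.4e-08; adjusted p = 0.228 with an estimated correlation). HIF targets outside glycolysis had a median of 0.24, with 0 called by limma, 9 adjusted over the list alone and 14 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 8.27e-05; adjusted p = 0.552 with an estimated correlation). Glycolysis and lactate export had a median of 0.29, with 0 called, 7 adjusted over the list alone and 8 higher unadjusted (camera adjusted p = 8.27e-05; adjusted p = 0.653 with an estimated correlation). Mitochondrially encoded mRNAs had a median of 0.34, with 2 of 13 called and 6 adjusted over the list alone (camera adjusted p = 0.000294; adjusted p = 0.597 with an estimated correlation; median 0.15 without 8% replicate 1). At 8% oxygen the list stood at 0.097 in replicate 2, which was nearer the 1% libraries (0.192, 0.197 and 0.103) than were replicates 1 and 3 (−0.321 and −0.257). DNA replication genes had a median of 0.34 with 33 of 36 positive. Of these limma called 0, 0 adjusted over the list alone, and 3 lay higher and 1 lower unadjusted (camera adjusted p = 8.27e-05; adjusted p = 0.729 with an estimated correlation). Cholesterol synthesis genes had a median of 0.21 with 22 of 23 positive, 0 called, 0 adjusted over the list alone and 4 higher unadjusted (camera adjusted p = 0.00142; adjusted p = 0.729 with an estimated correlation). Fry did not call glycolysis, mitochondrially encoded mRNAs, DNA replication or cholesterol synthesis (adjusted p = 0.137, 0.053, 0.462 and 0.462).

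**Figure D3:**
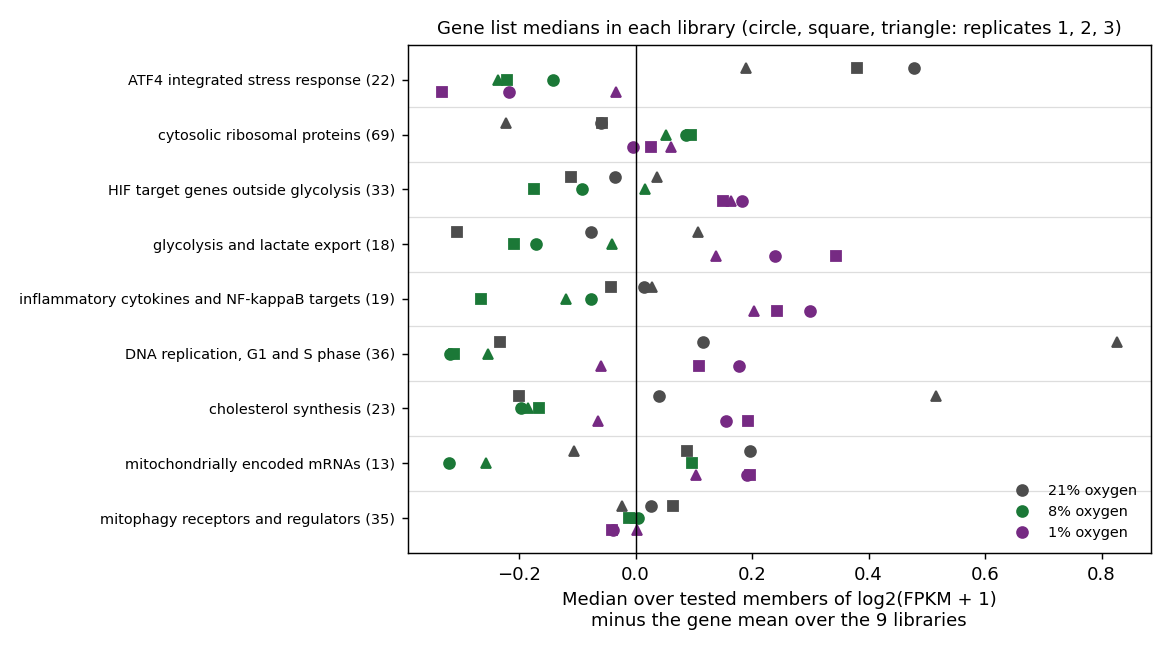
Median over the members of 9 gene lists of log2(FPKM + 1) minus each gene's mean over the 9 libraries, shown for every library by oxygen level. ATF4 genes lay above 0 in all 3 libraries at 21% oxygen and below 0 elsewhere, and DNA replication genes reached 0.826 in 21% replicate 3 alone.

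Another 6 lists rose at 1% against 8% oxygen with smaller shifts. Camera gave an adjusted p of 0.00762 for nuclear-encoded complex I (median 0.08; adjusted p = 0.667 with an estimated correlation) and 0.0231 for NRF2 targets and antioxidant enzymes (median 0.10; adjusted p = 0.653 with an estimated correlation). For interferon-stimulated genes it gave 0.0231 (median 0.19; adjusted p = 0.667 with an estimated correlation) and for mitochondrial protein import 0.0355 (median 0.07; adjusted p = 0.653 with an estimated correlation). For the endoplasmic reticulum unfolded protein response it gave 0.0451 (median 0.14; adjusted p = 0.729 with an estimated correlation) and for the mitochondrial ribosome 0.0451 (median 0.08; adjusted p = 0.667 with an estimated correlation). Cytosolic ribosomal proteins fell with a median of −0.05 (camera adjusted p = 0.0451; adjusted p = 0.864 with an estimated correlation). In these 7 lists limma called 0 members. At an unadjusted p under 0.05 there were 5, 4, 5, 9, 4 and 7 members of the rising lists higher, in the order given, against 0, 1, 1, 0, 1 and 4 lower, and 2 cytosolic ribosomal proteins lower against 1 higher. Adjusted over the list alone, 1 member each of the NRF2, interferon and mitochondrial ribosome lists passed and none of the others.

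The calls of the last 5 of these lists were kept in 15, 13, 10, 8 and 11 of 22 alternatives. Single libraries ended the calls of OXPHOS complex I, nuclear-encoded (1% replicate 2, adjusted p = 0.0956 without it) and NRF2 targets and antioxidant enzymes (1% replicate 3, 0.0518). That of interferon-stimulated genes ended without 8% replicate 1 or 3 or 1% replicate 2 or 3 (up to 0.0694), and that of mitochondrial protein import without 21% replicate 3, 8% replicate 3 or 1% replicate 2 or 3 (up to 0.0846). The endoplasmic reticulum unfolded protein response lost its call without 21% replicate 2 or 3, 8% replicate 1 or 1% replicate 3 (up to 0.403). For the mitochondrial ribosome this held for every library except 21% replicate 1 and 8% replicate 2 (up to 0.234), and for cytosolic ribosomal proteins for 21% replicate 2, 8% replicates 1 and 2 and 1% replicates 1 and 2 (up to 0.244). Medians went to 0.12 for complex I without 8% replicate 2, 0.03 for the mitochondrial ribosome without 8% replicate 3 and 0.05 for the unfolded protein response without 1% replicate 3. Fry kept none of these 7 calls.

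Limma called 15 genes between 1% and 8% oxygen, 8 higher and 7 lower, and 2247 at an unadjusted p under 0.05, while 3925 genes (33.11%, chance 10%) had groups that did not overlap. In a fit to only the 6 libraries of this comparison, which leaves out the more spread 21% libraries, 484 genes were called (265 higher, 219 lower), all 15 among them, and the median SE was 0.0804 in place of 0.0978. That fit called 7 HIF targets, 6 glycolysis genes, 12 DNA replication genes and 6 inflammatory genes higher at 1% oxygen, and 1 inflammatory gene lower (Ptgs2, −0.54, adjusted p = 0.037). It gave Bnip3 at 1.13 (adjusted p = 0.033), Pdk1 at 1.04 (0.0074) and Ldha at 0.92 (0.041). Leaving out 21% replicates 1, 2 and 3 gave 3, 123 and 435 calls in the fit to all levels, 8% replicates 1, 2 and 3 gave 3, 4 and 1, and 1% replicates 1, 2 and 3 gave 4, 7 and 3.

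Mitophagy receptors and regulators, the subject named in the series title, were tested as a list of 35 genes. As a list they showed no shift in one direction in any comparison. Fry's mixed test counts changes in either direction, without comparing members with other genes. It gave adjusted p = 1.77e-06 at 8% against 21%, 0.00367 at 1% against 21% and 0.0251 at 1% against 8% oxygen. Most of the 36 lists passed this mixed test at 8% and at 1% against 21%. Passing it therefore did not set the mitophagy list apart there. At 8% against 21% oxygen 2 of the 35 rose and 2 fell (2 and 0 adjusted over the list alone), with a median of −0.01, a mean of −0.03 and an upward camera direction (adjusted p = 0.651). Among all 11856 tested genes 993 rose and 1772 fell in that comparison. Calcoco1, a coiled-coil protein with a role in autophagy (ENSMUSG00000023055, chromosome 15, 102706777 to 102722178), rose from 10.7 ± 1.25 to 17.99 ± 0.141 FPKM (SD, n = 3, log2 fold change 0.70, SE 0.08, adjusted p = 0.00165). The autophagy kinase Ulk1 rose from 7.07 ± 0.516 to 9.73 ± 0.568 (0.41, SE 0.066, adjusted p = 0.00515). Atad3a, an inner membrane ATPase, fell by 0.48 (adjusted p = 0.0287) and Fkbp8, a mitophagy receptor, by 0.33 (adjusted p = 0.0351), calls lost in 8 and 9 of 19 alternatives (adjusted p up to 0.0934 and 0.112). Among these were, for Atad3a, leaving out 21% replicate 1 or 2 or any 8% library and, for Fkbp8, leaving out 21% replicate 1 or 3, 8% replicate 2 or 3 or 1% replicate 2. At 1% oxygen limma called 0 of 35 against 21%, 0 also when adjusted over the list alone, with 3 higher and 8 lower at an unadjusted p under 0.05. The median was −0.06 and the mean −0.03, beside a median of −0.0471 over all tested genes, and camera pointed up (adjusted p = 0.934, fry 0.146). Against 8% limma called 0, with 2 lower when adjusted over the list alone and 2 higher and 3 lower at an unadjusted p under 0.05 (median −0.04, camera adjusted p = 0.379; fry 0.219). The fit to the 6 libraries of that comparison called 1 higher (Bnip3) and 2 lower (Calcoco1 and Ulk1). At 8% against 21% the median turned to 0.03 after median-ratio rescaling and 0.04 after quantile normalization, and at 1% against 21% it was −0.01 and 0.0024.

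Single mitophagy genes were measured as follows. Bnip3, the HIF-induced mitophagy receptor (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519), stood at 34.9 ± 18.4 FPKM at 21%, 22.6 ± 4.13 at 8% and 50.5 ± 8.51 at 1% oxygen (SD, n = 3). Its log2 fold changes of −0.50 (SE 0.32, adjusted p = 0.289), 0.63 (0.281) and, at 1% against 8%, 1.13 (0.136) did not pass, and the 21% libraries alone ranged from 20.3 to 55.6 FPKM. Without 21% replicate 3, Bnip3 passed at 1% against 21% (1.02, adjusted p = 0.0337) and against 8% (0.0327). Its paralogue Bnip3l stood at 76.7 ± 12.6, 80.9 ± 8.46 and 93.6 ± 9.83 FPKM at 21%, 8% and 1% oxygen, and Fundc1, a receptor on the outer membrane, at 13.0 ± 0.691, 13.5 ± 0.372 and 14.2 ± 0.683. The kinase Pink1 stood at 16.8 ± 1.2, 19.4 ± 1.07 and 19.1 ± 1.25 FPKM. Limma called none of these 3 in any comparison (adjusted p between 0.0901 and 0.916). Pink1 passed at 8% against 21% after either rescaling (lowest adjusted p = 0.0447).

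Across the comparisons with 21% oxygen, 446 genes were called in the same direction at 8% and at 1% (136 higher, 310 lower) and 1, mt-Te, in opposite directions. Independent lists of these sizes would share 13.4 and 51.26. Simulations of unchanged groups that share simulated 21% libraries gave 0.01 on average. No gene changed in them, so hardly any could be called and a small overlap was fixed in advance. They do not show what unrelated real changes would share through the 21% libraries. The simulations also drew each gene independently, so they may understate what chance gives where genes vary together. Log2 fold changes of the 11856 genes correlated at 0.6785 across genes (0.4962 simulated), with a covariance of 0.05404 against 0.01365 simulated, a difference of 0.04039. The 3 libraries at 21% were not split between the comparisons, as a part with a single library has no spread of its own, and part of the excess may come from these shared libraries. Over all genes 76.39% had estimates of the same sign at 8% and at 1% (66.75% simulated). Of the 15 genes called between 1% and 8%, 13 differed at 8% in the same direction from both other levels, including Il1rl1 and mt-Cytb, and 3 (Lsm12, mt-Tl1 and mt-Te) did so at 1%. Both counts include mt-Te, which was lower at 8% and higher at 1% than at 21% (−0.23, adjusted p = 0.044; 0.39, adjusted p = 0.025). Its call between 1% and 8% was lost without any 8% or 1% library (adjusted p up to 0.143), without the filter on low values and with the replicate block. The moderated F test called 1928 genes across the 3 levels. Both counts rest on the spread shared by all 9 libraries. Fits to only the 6 libraries compared called 1606 genes at 8% and 64 at 1% against 21% oxygen, and their overlap was not computed. Leaving out single libraries moved the F test count and the count of shared genes. The F test called 821 without 21% replicate 1, 792, 1068 and 771 without 8% replicates 1, 2 and 3, and 1089 and 1170 without 1% replicates 1 and 2. The genes shared in direction numbered 72, 269 and 685 without 21% replicates 1, 2 and 3, 152 and 249 without 8% replicates 1 and 3, and 58, 67 and 187 without 1% replicates 1, 2 and 3.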

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

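The restriction to protein-coding genes, and the other settings run together with an estimated correlation, were chosen after the data had been seen and all other settings before. No call named by the 4 criteria changed direction in any setting run for it, and other named calls were not run. Of the calls named by the criteria, 86 of 140 at 8% against 21% oxygen, 12 of 54 at 1% against 21% and 1 of 13 at 1% against 8% were kept in every setting run for them. The mitophagy list was called as a shift in one direction in no setting. With both other pseudocounts, without the trend and with robust estimates every count of genes and lists stayed within 1.5 times its value.

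Without the filter on low values, 222 genes were called at 1% against 21% (76 higher, 146 lower), 4 at 1% against 8% (2 higher, 2 lower) and 1105 by the F test, with 195 shared by both comparisons with 21% and 11 lists called at 8% against 21%. That setting adds genes to the adjustment. At a mean of at least 5 FPKM, which tests fewer genes, 56 were called at 1% against 8% (30 higher, 26 lower) along with 8 lists. At 1% against 21%, median-ratio rescaling left 184 lower genes, and quantile normalization left 333 genes, 174 of them lower, and 296 shared. The cause of these 4 values was not tested. A fit to only the 6 libraries compared, with fewer samples, gave 1606 (565 higher, 1041 lower), 64 (28 and 36) and 484 (265 and 219) at 8% against 21%, 1% against 21% and 1% against 8%. A log2 fold change of at least 1 left 80 (40 and 40), 16 (9 and 7) and 3 (1 and 2), with 11 shared, by its construction. Camera with an estimated correlation called 0, 0 and 0 lists, also with each other filter, each rescaling, 6 libraries or protein-coding genes only, and fry called 10 at 8% against 21% and 3 at 1% against 8%. These differ in what they test. Protein-coding genes alone gave 529 lower genes at 1% against 21% and 39 genes at 1% against 8% (19 higher, 20 lower), from fewer genes tested.

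With 1 library left out at a time, the calls ranged from 1479 to 2987 at 8% against 21% (higher 548 to 1134, lower 931 to 1853), from 63 to 883 at 1% against 21% (22 to 271, 39 to 612) and from 1 to 435 at 1% against 8% (0 to 238, 1 to 197). The F test called 771 to 2251 genes and 58 to 685 were shared. Lists called numbered 5 to 9, 9 to 14 and 8 to 13 in the order above, and 0 in each with an estimated correlation. The median of the mitophagy list lay between −0.0248 and 0.0124, −0.0622 and −0.0133, and −0.0532 and −0.0222. Fewer libraries lower the power. Leaving out 21% replicate 3 gave the 883, 435, 2251 and 685. At 1% against 8% that library enters only through the shared estimate of the spread. The rise there from 15 to 435 therefore came through that estimate. The cause of the other rises without it was not tested.

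Replicate numbers recur across the oxygen levels without the labels saying that they pair libraries. Of 9 same-number pairs, 0 had deviations correlated over 0.1 (−0.303 to 0.095), and 2 of 9 libraries were closest to one with their own number. With the replicate block, 1849 genes were called at 8% against 21% (667 higher, 1182 lower), 72 at 1% against 21% (31 and 41), 1 at 1% against 8% (0 higher, 1 lower) and 756 by the F test, 66 were shared, and 5, 10 and 12 lists were called. The block takes up residual degrees of freedom. Sequencing depth is unknown, so it is also unknown how far low depth limits genes with few reads.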

Other observations

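Of the tests below, those of a left-out library or another filter with an estimated correlation, those of a swap and of scaling for 21% replicate 3, those of the mitochondrial tRNA genes and that of the YAP/TAZ target genes were chosen only after the result was seen. Several gene groups not described so far held single genes that differed between 8% and 21% oxygen although no list passed camera. In the BCL2 family, regulators of apoptosis, 1 of 13 rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.424). The pro-apoptotic Bmf rose from 1.64 ± 0.00553 to 3.72 ± 0.443 FPKM (SD, n = 3, limma log2 fold change 0.84, adjusted p = 0.00143), while the pro-apoptotic Bid fell from 13.9 ± 1.11 to 8.85 ± 0.492 (−0.60, adjusted p = 0.00243) and the anti-apoptotic Bcl2 from 2.23 ± 0.276 to 1.39 ± 0.0795 (−0.43, adjusted p = 0.00901). Of 24 NRF2 targets and antioxidant enzymes 2 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.365), among them the iron store Fth1 (−0.44, adjusted p = 0.00655) and Gclc of glutathione synthesis (−0.48, adjusted p = 0.0116). Of 22 extracellular matrix and basement membrane genes 5 rose and 3 fell (5 and 5 adjusted over the list alone). Their median was 0.045 and their mean −0.002, and camera pointed up (adjusted p = 0.365). The collagenase Mmp13 fell from 139 ± 16.9 to 81.6 ± 2 FPKM (−0.76, adjusted p = 0.00243) and the gelatinase Mmp9 by 0.62 (adjusted p = 0.00679). In the autophagy machinery 5 of 33 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.25), with Map1lc3a of the LC3 family higher (0.37, adjusted p = 0.0114) and the conjugating enzyme Atg3 lower (−0.41, adjusted p = 0.00472). Lysosome genes gave 3 higher of 26 (2 adjusted over the list alone; camera adjusted p = 0.155), with the sialidase Neu1 at 9.46 ± 0.116 against 5.74 ± 1.3 FPKM (0.65, adjusted p = 0.0102). Interferon-stimulated genes gave 4 lower of 16 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.29, and 0.00501 without the filter on low values, where an estimated correlation gave 0.548), with the antiviral sensor Oas1a at −0.77 (adjusted p = 0.00401). The named calls of this paragraph were kept in every alternative run for them.

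Some genes lay lowest at 8% oxygen. Csf3 averaged 128 ± 59, 34.0 ± 2.94 and 108 ± 10.9 FPKM at 21%, 8% and 1% oxygen (SD, n = 3). A limma fit to only the 6 libraries at 8% and 1% called it higher at 1% (1.64, adjusted p = 0.0045), together with the chemokine Cxcl1 (156 ± 15.7 against 75.0 ± 3.04, 1.04, adjusted p = 0.0077). In the fit to all 9 libraries their adjusted p was 0.065 and 0.076, and libraries were not left out of the smaller fit. The cell cycle gene Ccnd1 and the ETS factor Etv5, chosen after their values were seen, fell at 8% against 21% oxygen (−1.24, adjusted p = 0.0082; −1.49, adjusted p = 0.0013), and Ccnd1 lay at 77.5 ± 4.94 FPKM at 1% against 41.7 ± 0.511 at 8% (0.88, adjusted p = 0.0053 in the smaller fit and 0.12 in the larger). Of 16 heat shock genes limma called 0 between 1% and 8%, with 5 lower when adjusted over the list alone and 6 lower at an unadjusted p under 0.05 (median 0.003, mean −0.19, camera adjusted p = 0.0701 and pointing down; fry 0.0112; camera 0.0301 without 1% replicate 2, and 0.425 there with an estimated correlation).

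The library of 21% replicate 3 stood apart in proliferation genes. In DNA replication, G1 and S phase 35 of 36 members were highest there, and the median deviation of cell cycle, G2 and M phase genes was 0.568 there against −0.143 and −0.557 in 21% replicates 1 and 2. Without it, the G2 and M list was called higher at 1% against 21% (camera adjusted p = 1.22e-08, in place of 0.0826; adjusted p = 0.481 with an estimated correlation) and at 8% against 21% (2.94e-05, in place of 0.365; adjusted p = 0.747 with an estimated correlation), set against 2 libraries that include the low 21% replicate 2. The tables argued against 3 technical explanations: a swap, as 0 libraries of 8% or 1% oxygen correlated better with 21% replicates 1 and 2 than with their own group; scaling, as the median deviation of DNA replication genes was 0.826 before and 0.799 after quantile normalization; and cells of another type, as 0 of 85 markers of other cell types, 18 of them at 1 FPKM or more, reached 2 times their highest value elsewhere. Its mean r was 0.9753 with the 1% libraries and 0.9737 with 21% replicates 1 and 2, so correlation alone leaves a wrong label open. Genes called at 1% against 21% with and without it argue against a 1% or 8% library under its label. Mapk14 read 17.7 FPKM in it (17.0 and 17.7 in 21% replicates 1 and 2, at most 7.89 at 1% and 7.65 at 8%). There Slc39a14 read 15.85 (16.5 and 15.7, at most 8.19 and 5.74) and mt-Tc 9.21 (10.4 and 9.96, at least 33.1 and 33.5). These genes were named for groups that did not overlap, this library included. No biological explanation was tested.

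The light-strand tRNA genes mt-Ta, mt-Tn, mt-Tc and mt-Ty, neighbours on the mitochondrial genome (M, 5018 to 5326), were all called higher at both reduced oxygen levels, mt-Ty by 1.18 and 1.07 (adjusted p = 0.0023 and 0.014; the call at 1% was lost without 21% replicate 1 or 1% replicate 1 and with the replicate block, up to 0.0612). Higher readings of short genes are argued against by the median of the other 242 tested genes under 200 nt (−0.016 at 8% and −0.096 at 1%). More mitochondrial RNA of every kind is argued against by that of the 13 mitochondrial mRNA genes (−0.238 and 0.009). A rise of mitochondrial tRNA genes in general was not tested. The tRNA genes mt-Tt (1.13 at 8% and 1.14 at 1%) and mt-Tr (0.94 and 0.72) also lay higher. At 8% mt-Tk (−1.23), mt-Th (−0.38), mt-Tl1 (−0.36), mt-Te (−0.23) and mt-Tl2 (−0.06) lay lower, and at 1% only mt-Tk did (−0.05). More light-strand transcription along the whole genome as the whole cause was tested on the other 3 tested light-strand genes (median 0.046 at 8% and 0.392 at 1%). Of these, mt-Nd6 (95% intervals −0.19 to 0.29 and 0.15 to 0.63) and mt-Te (−0.38 to −0.07 and 0.24 to 0.55) stayed below 1. That would argue against it if reads were counted by strand, but the strand setting is unknown. The estimates of mt-Nd6 (0.05 and 0.39) were close to those of the overlapping heavy-strand mt-Nd5 (0.04 and 0.41). Counted without strand, mt-Nd6 and mt-Te could not test light-strand transcription, so the explanation stays open. The third gene, mt-Tp (1.31, adjusted p = 0.037; 0.64, adjusted p = 0.34), went with it at 8%, a call lost without 21% replicate 1, any 8% library or 1% replicate 1 or 2 (up to 0.0988). All 3 estimates were positive at 1%. Precursor reads of the heavy strand between mt-Nd2 and mt-Co1, counted without strand, may still account for the pattern. The heavy-strand mt-Tw of the same interval stood at 0.828 at 8% (0.21 to 1.45, adjusted p = 0.059) and 1.05 at 1% (adjusted p = 0.064), which decides nothing.

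Ccn1, Ccn2, Thbs1, Amotl2 and Ankrd1 were all called higher at both reduced oxygen levels, Amotl2 at 27.5 ± 3.66, 50.2 ± 0.41 and 48.8 ± 2.09 FPKM at 21%, 8% and 1% oxygen (SD, n = 3). The last 2 genes were chosen after their values were seen, and Ccn2 passed narrowly at 8% (0.57, adjusted p = 0.042). A rise of YAP/TAZ-TEAD target genes is a candidate explanation, tested on 19 other targets listed from memory after these data and some of their values had been seen. The 14 tested had a median of 0.227 at 8% and 0.138 at 1% against 21% oxygen and, adjusted together with the 36 lists fixed in advance, passed camera at 1% (adjusted p = 0.0422; adjusted p = 0.418 with an estimated correlation) but not at 8% (adjusted p = 0.074; adjusted p = 0.701 with an estimated correlation), where F3, Crim1 and Tgfb2 rose and Axl and Nt5e fell. The hypothesis therefore stays open, and technical explanations of the pattern were not tested.

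Regrouping the libraries gave the following values. For each pair of oxygen levels there are 10 splits of the 6 libraries, too few for a share under 0.05. The real and the highest other number of called genes were 2765 and 3 at 8% against 21%, 503 and 2 at 1% against 21% and 15 and 2 at 1% against 8%, with 1 split of 10 as large in each. For called lists they were 5 and 10, 9 and 11, and 13 and 12, with 8, 5 and 1 splits as large, and for the size of the mitophagy median 0.0103 and 0.0311, 0.0574 and 0.0468, and 0.0399 and 0.0289, with 6, 1 and 1. The numbers of lists called against 21% oxygen were thus within what regrouping gave. Among 100 drawn splits of the 9 libraries, 1, the real one, reached the 1928 genes of the F test (highest other 227) and 1, again the real one, the 446 shared calls (highest other 202). At 1 of 100 splits, a random regrouping of these libraries is an unlikely source of both counts. Regrouping cannot test chance between cultures, as the labels do not say whether replicates were separate cultures.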
